A study of Mus musculus with 9 samples.

How the data were processed

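RNA sequencing had been done on mammary tumors of female mice carrying the MMTV-PyMT and human MUC1 transgenes, 4 with intact Hspa1a and Hspa1b (WT) and 5 lacking them (KO). Per the labels' protocols, tumors were minced and dissociated with collagenase and trypsin at 37 °C, passed through a strainer and pelleted before RNA was extracted. Ribosomal RNA was then depleted, and stranded libraries were sequenced as paired ends. Because tissue was dissociated first, losses of particular cell types and a response to dissociation can both enter the measurements.

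Per the submitters' processing notes, Trimmomatic 0.36, FastQC 0.11.5, STAR 2.5.4a and the mouse build GRCm38 were used; their order and settings are not given in the sources used here. The deposited table gives unnormalized counts per gene and library, in the layout of STAR's gene counting, which takes uniquely mapped fragments that lie within 1 gene. The annotation release and the strand setting are not given in the sources used here. Reads that match several genes equally well are not counted, so levels of genes with near-identical copies, such as Hspa1a, Hspa1b and pseudogenes, are uncertain. The table also held entries for the PyMT and human MUC1 transgenes.

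Entries that name no gene were kept out of library sizes and tests. They took 11.0% to 27.1% (unmapped), 5.50% to 9.53% (multimapped), 34.0% to 50.4% (no annotated feature) and 0.971% to 1.23% (ambiguous) of the fragments of a library. Of 55401 mouse gene identifiers, 55141 were matched to a symbol in the reference annotation of GRCm38 and 260 were not, and positions were taken from the same annotation. Groups were taken from the labels. A level allowed by 0 counts was taken as 3 counts of a library's gene total; such floors cover counting error only, since reads are not independent molecules.

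Differences between KO and WT were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the counts, with TMM factors, the filterByExpr filter and genotype as the only term. Benjamini-Hochberg adjusted p-values under 0.05 over the 14665 genes tested were called, all tests being two-sided. The SE of a log2 fold change was taken as its size over the square root of the F statistic. Printed CPM values are counts scaled to library size, using totals over the tested genes times the TMM factors, while floors use totals over all genes. Single levels were compared by exact permutation, whose smallest possible p is 0.00794 for 126 assignments. Of 36 gene lists, the 33 with at least 4 members tested were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset at 0.01 and adjustment over the lists. An estimated correlation, fry and exact permutation of library means were also run.

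The groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names Hspa1a and Hspa1b, then up to 12 called genes per direction with an average log2 CPM of at least 1, leaving out predicted genes and pseudogenes, then up to 4 members of each list with the smallest unadjusted p. The alternatives chosen at that stage were DESeq2 1.42.0, limma-voom with sample weights, other scaling factors, no count filter or a mean count of at least 50, the library number as a block, age as a covariate, other thresholds and each library left out in turn. Further alternatives were chosen after seeing the data: leaving out WT 1 and WT 4, which had the highest casein counts, leaving out chromosomes 14 and 17, the HSP70 list without Hspa1a, Hspa1b and Hspa1l, the permutation of list means, and a correction of each library for exon length and GC content.

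The tests were tested on simulated data with the libraries' own depths and means, 200 of 14665 genes changed between KO and WT, and genes drawn independently. For changes of 2-fold, edgeR recovered 102 of the 200 with 9 false calls, DESeq2 133 with 36 and limma-voom 101 with 10. For changes of 4-fold the numbers were 188 with 8, 192 with 31 and 184 with 10. A simulated list shifted by 1.5-fold had an adjusted p of 1.02e-13 with the preset correlation, 0.00182 with an estimated correlation and 0.000111 by fry, and no other list was called. Independent genes favor the preset correlation of 0.01, so this does not test the preset calls in the data. There the estimated correlation was 0.25 for the collagens and 0.38 for the matrix glycoproteins.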

Results

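Mammary tumors that arose in female MMTV-PyMT mice were profiled by RNA sequencing. In these mice a mammary tumor virus promoter drives the polyoma middle T oncogene, and the animals also carried a human MUC1 transgene on a C57BL/6 background. The series asks which processes in the tumors depend on HSP72, the stress-inducible HSP70 chaperone encoded by the neighbouring genes Hspa1a and Hspa1b, with matrix production named in its title. Tumors with both genes intact (WT) gave 4 libraries, and tumors lacking them (KO) gave 5. The WT animals were 122 to 132 days old and the KO animals 120 to 125 days old. Only WT 2, at 132 days, was older than 125 days, so age as a covariate rests largely on that library. The labels describe 9 tumor samples without animal numbers, so p-values measure the spread between these samples. Each library held 11500920 to 19136317 fragments, of which 4410399 to 6221181 were counted on genes. A count of 0 in a library allowed up to 0.482 to 0.680 CPM, the count scaled to library size, taken as 3 counts and covering counting error only.

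The targeted genes were read first, as a check of the labels. Hspa1b (ENSMUSG00000090877.3, chromosome 17, 34956436 to 34959238, GRCm38) stood at 55.0 ± 22.3 CPM in WT (SD, n = 4) and 0.203 ± 0.269 CPM in KO (SD, n = 5). Its counts summed to 1043 over the WT libraries and 6 over the KO libraries, and it fell by 7.89 ± 0.51 on the log2 scale (SE; edgeR quasi-likelihood adjusted p = 5.31e-05). Hspa1a (ENSMUSG00000091971.3, chromosome 17, 34969190 to 34972156) stood at 7.36 ± 2.66 CPM in WT and 0.789 ± 0.578 CPM in KO, from 139 and 23 counts in all. Hspa1a fell by 3.16 ± 0.47 on the log2 scale (SE; edgeR adjusted p = 0.0342). Both genes were lower in every KO library than in every WT library. Their coding sequences are nearly identical, so the division of reads between them is uncertain. The adjacent HSP70 gene Hspa1l (ENSMUSG00000007033.4, 34972703 to 34979285), whose product is best known from the testis, rose from 0.417 ± 0.323 CPM in WT to 15.5 ± 4.00 CPM in KO, a log2 fold change of 5.16 ± 0.40 (SE; edgeR adjusted p = 0.000166). The call for Hspa1a was lost in 7 of the 9 fits that left out 1 library, with adjusted p of up to 0.125, and with age as a covariate (0.0858), while those for Hspa1b and Hspa1l were kept in all 9.

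The oncogene and the human transgene were carried at similar levels in both groups. PyMT reads made up 8730 ± 1640 CPM in WT and 10968 ± 2834 CPM in KO (SD), a log2 fold change of 0.33 ± 0.22 (SE), which was within the spread between libraries (exact permutation p = 0.214, two-sided). The human MUC1 row stood at 777 ± 387 CPM in WT and 767 ± 217 CPM in KO (exact permutation p = 0.937, two-sided). Mouse Muc1, the endogenous gene for this epithelial mucin, was lower in every KO library, at 93.7 ± 8.13 CPM against 158 ± 41.3 CPM in WT. Its log2 fold change of -0.76 ± 0.16 (SE) gave an edgeR adjusted p of 0.242, and an exact permutation p of 0.00794, the smallest that 126 assignments can give. DESeq2 called mouse Muc1 lower (adjusted p = 0.00819).

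**Figure D1:**
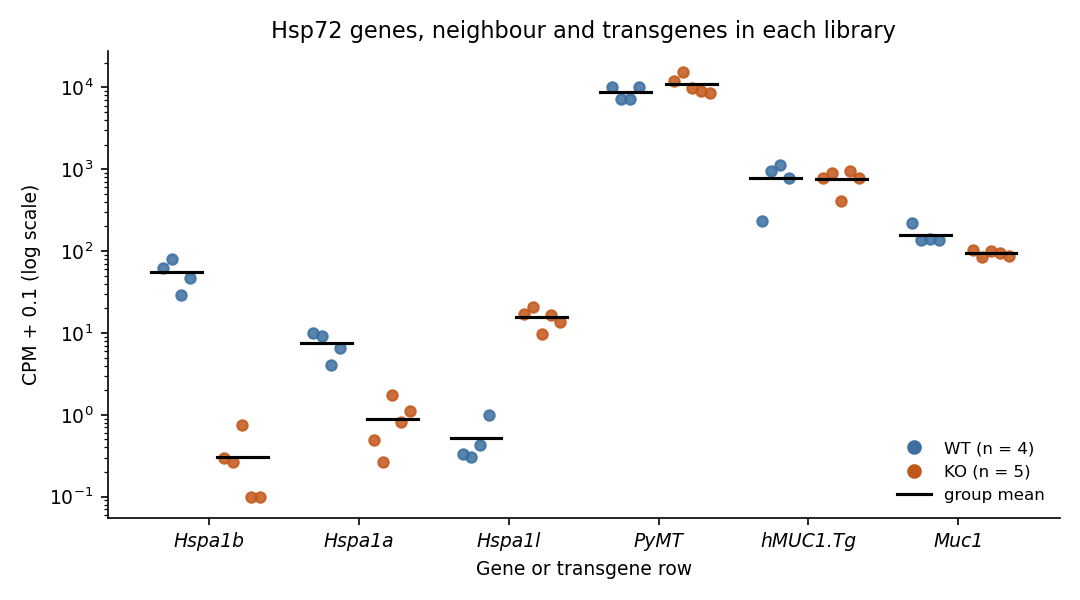
CPM of Hspa1b, Hspa1a, Hspa1l, the PyMT and human MUC1 transgenes and mouse Muc1 in each library, on a log scale after adding 0.1, with WT in blue, KO in orange and bars at the group means. The KO libraries lie below every WT library for Hspa1b and Hspa1a and above every WT library for Hspa1l, while the groups overlap for both transgenes.

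Few single genes separated the genotypes. Of 14665 genes tested, 8 were higher and 5 lower in KO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1166 had an unadjusted p under 0.05, of which 493 were higher and 673 lower. Of the 13 genes called, 7 lay on chromosome 14, 3 were the Hsp72 genes and Hspa1l on chromosome 17, and 3 lay elsewhere. Every KO library exceeded every WT library for 211 genes and lay below every WT library for 185, together 2.70% of the genes tested where chance gives 1.59%. The calls for 6 of the 13 genes were kept whichever library was left out, and the number called then ranged from 6 to 13.

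The chromosome 14 genes moved in both directions between 54292443 and 70636048. Xkr6 (ENSMUSG00000035067.9, 63606503 to 63820809), a member of the XK-related membrane protein family, rose from 2.13 ± 0.341 CPM in WT to 70.2 ± 17.3 CPM in KO (SD), a log2 fold change of 5.04 ± 0.25 (SE; edgeR adjusted p = 4.64e-06). Its neighbour Mtmr9 (63519651 to 63543982), a myotubularin-related protein, rose from 34.5 ± 5.03 to 155 ± 29.1 CPM (log2 fold change 2.17 ± 0.17). Phyhip (70457476 to 70468832) rose from 0.266 ± 0.135 to 5.51 ± 1.20 CPM and Dmtn (70601263 to 70636048), which encodes the actin-binding protein dematin, from 7.60 ± 3.49 to 33.5 ± 4.49 CPM, with log2 fold changes of 4.30 ± 0.38 and 2.13 ± 0.29. Ppp1r3e (54872669 to 54877550), a regulatory subunit of protein phosphatase 1, fell by 2.00 ± 0.28 on the log2 scale, from 6.90 ± 1.78 to 1.71 ± 0.465 CPM. The transcripts Gm15918 and Gm43305 fall outside the rule for named genes and were chosen after their values were seen. Gm15918 is annotated antisense and shares 326 of its 689 exon bases with Xkr6. It had 0 counts in WT and 70 in KO, at 2.45 ± 0.611 CPM in KO (SD). A count of 0 allowed up to 0.525 to 0.680 CPM in the WT libraries, taken as 3 counts. Reads in the shared bases cannot be told from those of Xkr6 because the strand setting of the counting is not given in the sources used here. Gm43305 had 225 counts in WT and 3 in KO, with 34.0 CPM in WT 4 and 3.49 to 7.52 CPM in the other WT libraries. Leaving out 1 library ended the calls for Dmtn and Gm43305 in 6 of 9 fits and Ppp1r3e in 8, with adjusted p of up to 0.106, 0.194 and 0.107. Age as a covariate also ended the calls for Gm43305 and Ppp1r3e (adjusted p = 0.0858 for both). Gm15918 lost its call in 5 fits, with adjusted p of up to 0.0888, and fell under the count filter in 2.

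**Figure D2:**
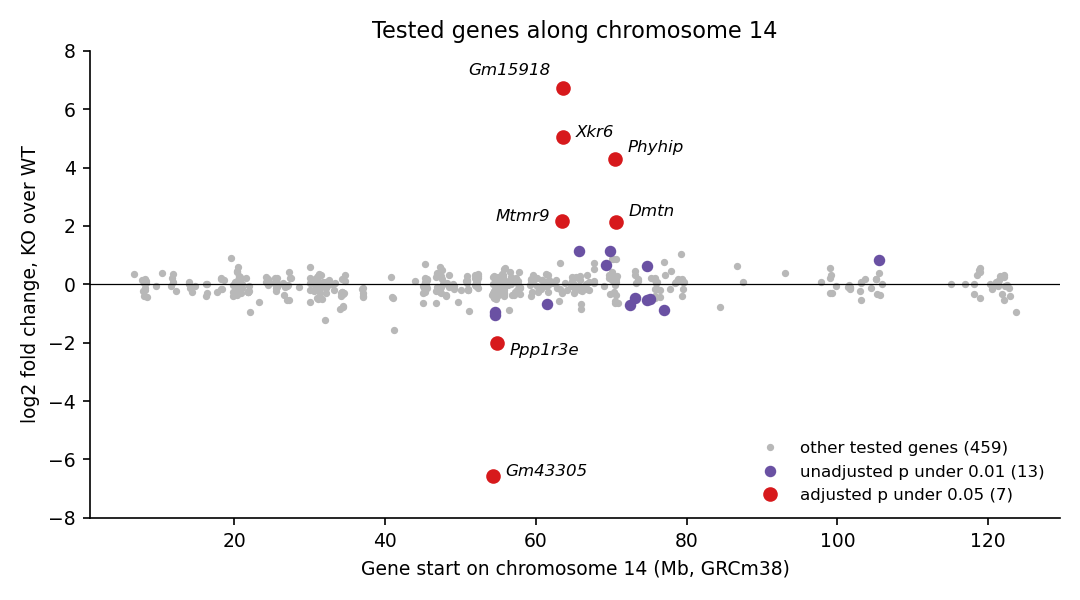
log2 fold change, KO over WT, of the 479 tested genes of chromosome 14 against the position of their start in Mb (GRCm38). The 7 genes past the adjusted threshold are red, 13 others with an unadjusted p under 0.01 are purple and the rest are grey; called genes lie on both sides of 0.

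The remaining called genes were Cilp and a pair of pseudogenes. Cilp (ENSMUSG00000042254.14, chromosome 9, 65265180 to 65280605) encodes cartilage intermediate layer protein, a secreted matrix protein. It fell by 1.19 ± 0.17 on the log2 scale (SE; edgeR adjusted p = 0.0259), from 35.8 ± 6.25 CPM in WT to 15.7 ± 2.65 CPM in KO. Among the 9 fits that left out 1 library its call was kept only without WT 4, with adjusted p of 0.0503 to 0.124 in the other 8, and it was lost with age as a covariate (0.0869). The pseudogenes fall outside the rule for named genes and were chosen after their values were seen. Gm3375 (chromosome 7, 3181093 to 3181888), a processed copy of the proteasome subunit gene Psmb5 with 98.9% identity over the aligned bases, had 0 counts in WT and 166 in KO. It stood at 5.78 ± 0.649 CPM in KO (SD), against floors of 0.525 to 0.680 CPM in the WT libraries. Gm28438 (chromosome 1, 24612775 to 24613119), which is identical to the mitochondrial gene mt-Nd3 over 342 of its 345 bases, had 4 counts in WT and 169 in KO. Reads that match a copy and its parent gene equally well are not counted, so the levels of such copies are uncertain. The Gm28438 call was lost in 6 of 9 fits that left out 1 library, with adjusted p of up to 0.0658.

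Genes of the extracellular matrix were lower in KO tumors as a group. Of 21 fibrillar, network and other collagens tested, 19 had negative fold changes, and their median log2 fold change was -0.62. The type I chains Col1a1 and Col1a2 had log2 fold changes of -1.06 ± 0.26 and -1.12 ± 0.23 (SE), and the type V chains Col5a1 and Col5a2 -0.86 ± 0.21 and -0.86 ± 0.22. In edgeR none of the 21 passed over all genes tested and 9 had an unadjusted p under 0.05, all lower; the same number passed adjusted over the list alone, and DESeq2 called 3 over all genes. The camera test with its correlation preset at 0.01 called the list lower (adjusted p = 6.09e-09 over 33 lists), whereas adjusted p = 0.289 with an estimated correlation. The mean log2 CPM of the collagens was 6.41 ± 0.107 in the WT libraries and 5.84 ± 0.295 in the KO libraries (SD). The KO libraries lay between 5.37 and 6.19 and the WT libraries between 6.31 and 6.55.

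Non-collagen matrix genes were also lower, by an amount that rested in part on WT 1. Of 29 matrix glycoproteins and proteoglycans, 27 had negative fold changes, with a median of -0.63, and of -0.31 without WT 1, where that of the collagens was -0.53. Biglycan (Bgn) had a log2 fold change of -1.23 ± 0.31 (SE), the collagen-binding Sparc -1.26 ± 0.34, fibrillin 1 (Fbn1) -0.91 ± 0.27 and elastin (Eln) -0.73 ± 0.18. Adjusted over the list alone these 4 genes passed. Over all genes edgeR called none, 13 had an unadjusted p under 0.05, and DESeq2 called 1. The list was lower by camera with the preset correlation (adjusted p = 6.09e-09), and adjusted p = 0.289 with an estimated correlation. Bgn, Sparc and Fbn1 were highest in the same library, WT 1, at 92.1, 250 and 132 CPM, against at most 39.4, 100 and 61.5 CPM in the other WT libraries. Their log2 fold changes without it were -0.74, -0.74 and -0.50. Without WT 1 the camera adjusted p of this list was 0.000168, and without WT 1 and WT 4 it was 0.00254.

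Other matrix-related lists were lower by the preset camera test with smaller shifts. The median log2 fold change was -0.45 for 18 genes of collagen processing and crosslinking (camera adjusted p = 5.73e-05), -0.36 for 21 cell-matrix receptors (0.00114), -0.29 for 18 matrix proteases and inhibitors (0.00199) and -0.21 for 14 basement membrane genes (0.0291). With an estimated correlation their adjusted p-values were 0.289, 0.387, 0.316 and 0.377. Adjusted over the list alone, the gelatinase Mmp2 (-1.24 ± 0.31 SE) and the laminin chain Lamb3 (-0.87 ± 0.22) passed, and no receptor or processing gene did. Without WT 1 the medians of the processing genes, receptors, proteases and basement membrane genes were -0.20, -0.00018, -0.061 and -0.072, with camera adjusted p of 0.0135, 0.358, 0.126 and 0.358. The basement membrane call was also lost without KO 3 (0.0905) or KO 5 (0.144) and with age as a covariate (0.121). Without WT 3 or WT 4 the basement membrane median was -0.35 or -0.40, and without KO 3 -0.42. Without WT 1 and WT 4 the receptors, proteases and basement membrane genes had adjusted p of 0.198, 0.240 and 0.426. The 7 EMT genes tested had a median of -0.35, which was -0.054 without WT 1 and -0.53 without KO 3 (camera adjusted p = 0.0175, against 0.241, 0.0531 and 0.104 without WT 1, WT 4 or KO 1, 0.646 without WT 1 and WT 4 and 0.0842 at a mean count of at least 50; adjusted p = 0.303 with an estimated correlation). The 16 genes of the TGF-beta pathway had a median of -0.09, with -0.15 to -0.056 when 1 library was left out, the ends being WT 2 and KO 5 (0.0291, against 0.104 and 0.0644 without WT 1 or KO 1, 0.240 without WT 1 and WT 4, 0.0582 with age as a covariate and 0.0516 at a mean count of at least 50; adjusted p = 0.289 with an estimated correlation). The 14 YAP/TAZ targets had a median of -0.09 and were not called (camera adjusted p = 0.509). Their median was -0.28 without KO 4 and 0.00093 without KO 1, and no fit that left out 1 library called the list.

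**Figure D3:**
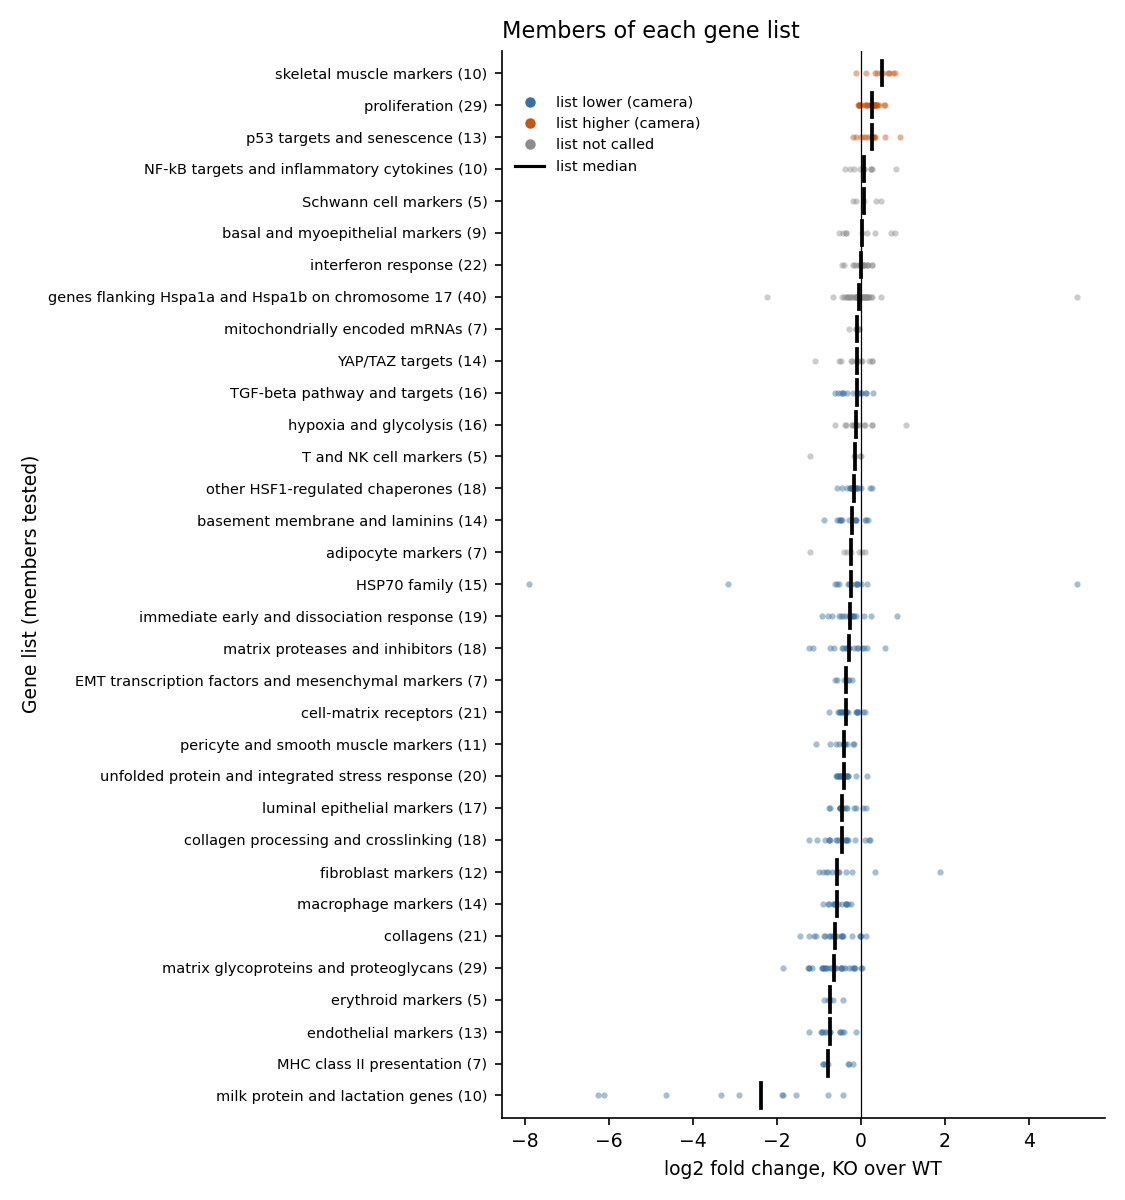
log2 fold change, KO over WT, of each tested member (points) of the 33 gene lists tested, with black bars at list medians. Blue lists were lower and orange lists higher by camera with a preset correlation, and grey lists were not called; no list was called with an estimated correlation.

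Markers of fibroblasts, pericytes, endothelium and macrophages and MHC class II genes were lower alongside the matrix genes by the preset camera test. The median log2 fold change was -0.57 for 12 fibroblast markers (camera adjusted p = 0.00256), -0.39 for 11 pericyte and smooth muscle markers (0.00196, and 0.107 with age as a covariate), -0.73 for 13 endothelial markers (4.67e-05), -0.57 for 14 macrophage markers (1.73e-06) and -0.78 for 7 genes of MHC class II presentation (0.00133). With an estimated correlation the adjusted p-values were 0.289, 0.289, 0.316, 0.289 and 0.316. Among fibroblast markers Pdgfrb had a log2 fold change of -0.89 ± 0.35 (SE) and Pdpn -0.68 ± 0.26, while the hyaluronan synthase Has2 had 1.88 ± 0.67. All 13 endothelial markers were negative, including the VEGF receptor Flt1 (-0.82 ± 0.34), and all 14 macrophage markers were negative, including the lipopolysaccharide co-receptor Cd14 (-0.89 ± 0.22), the only macrophage marker that passed adjusted over the list alone. Without WT 1 the fibroblast and endothelial medians were -0.30 and -0.23 (camera adjusted p = 0.0256 and 0.0135) and the change of Flt1 was -0.50. The endothelial and MHC class II calls were lost without WT 1 and WT 4, with adjusted p of 0.208 and 0.240, and the fibroblast and endothelial calls at a mean count of at least 50 (0.196 and 0.0516). The 5 T and NK cell markers tested had a median of -0.14 (camera adjusted p = 0.0902) and the 7 adipocyte markers -0.22 (0.302, and lower at 0.00668 without WT 1 and 0.000343 without WT 1 and WT 4), with lipoprotein lipase (Lpl, -1.21 ± 0.31) passing adjusted over that list alone. With 1 library left out the T and NK median ran from -0.60 (without KO 5) to 0.26 (without KO 3). The adipocyte median ran from -0.43 (without WT 1) to 0.12 (without WT 2). Of the B cell list only Ighm was tested (-0.39 ± 0.43). The 3 dendritic cell markers and 3 neutrophil markers tested, too few for a list test, had medians of -0.34 and 0.01. Lactoferrin (Ltf), on the neutrophil list and also made by mammary epithelium, had a log2 fold change of -1.02 ± 0.22. The 5 erythroid markers had a median of -0.73, and of -0.29 without WT 4 (camera adjusted p = 0.0175, against 0.0681, 0.183, 0.0765 and 0.126 without WT 2, WT 4, KO 2 or KO 3, 0.0668 without WT 1 and WT 4 and 0.215 with age as a covariate; adjusted p = 0.408 with an estimated correlation). The 5 Schwann cell markers had a median of 0.07 (camera adjusted p = 0.371), which ran from -0.052 (without WT 1) to 0.23 (without WT 4).

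Milk protein genes were lower in KO, and the levels of some divided the WT libraries. All 10 members tested were negative with a median log2 fold change of -2.38, and 9 passed adjusted over the list alone, among them alpha-lactalbumin (Lalba, -1.55 ± 0.34 SE), whey acidic protein (Wap, -3.32 ± 0.87) and the casein Csn1s2a (-6.25 ± 1.47). Wap stood at 84.9 and 71.4 CPM in WT 1 and WT 4, but at 1.88 and 6.48 CPM in WT 2 and WT 3 and 1.63 to 6.24 CPM in the KO libraries. Csn1s2a stood at 513 and 1267 CPM in WT 1 and WT 4, but at 2.30 and 6.48 CPM in WT 2 and WT 3 and 1.88 to 12.1 CPM in the KO libraries. Lalba did not divide them in this way, at 1283, 413, 484 and 612 CPM in WT 1 to WT 4. It stood at 166 to 355 CPM in the KO libraries, and its log2 fold change without WT 1 and WT 4 was -0.92. Over all genes edgeR called none of the 10, 9 had an unadjusted p under 0.05, and DESeq2 called 3. The mean log2 CPM of the list was 8.88 in WT 1 and 9.19 in WT 4, against 4.97 in WT 2 and 5.72 in WT 3 and 4.47 to 5.66 in the KO libraries. The camera adjusted p was 1.73e-06 with all libraries (adjusted p = 0.289 with an estimated correlation). It was 0.426 without WT 1 and WT 4, and the changes of Wap and Csn1s2a were then -0.07 and 0.38. These libraries were left out for their casein counts, which fixes that outcome. The 17 luminal markers had a median of -0.45, and of -0.18 without WT 2 (camera adjusted p = 0.00356, against 0.244 without WT 2 and 0.371 with age as a covariate; adjusted p = 0.289 with an estimated correlation). Among them E-cadherin (Cdh1) stood at -0.45 ± 0.19 (-0.24 without WT 1). The 9 basal and myoepithelial markers had a median of 0.02 and were not called (camera adjusted p = 0.644), the test's own direction being down. With 1 library left out their median ran from -0.24 (without KO 3) to 0.18 (without WT 2).

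**Figure D4:**
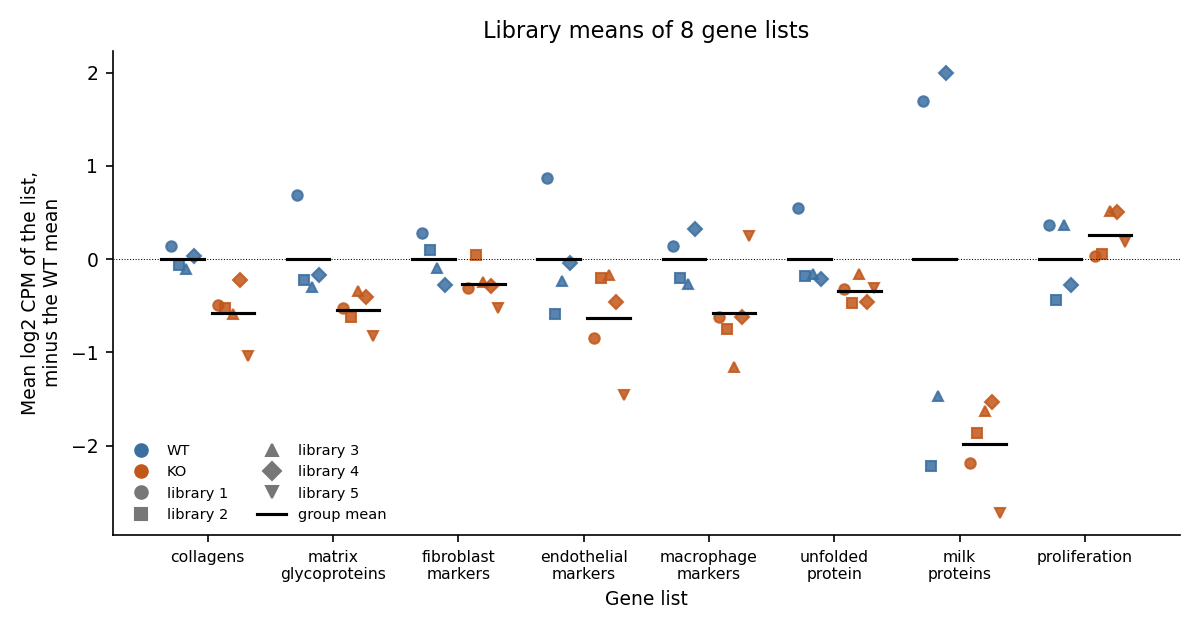
Mean log2 CPM of 8 gene lists in each library, relative to the WT mean of that list, with WT in blue, KO in orange, symbols for library numbers and bars at group means. The collagen means of the KO libraries lie below those of the WT libraries, whereas the milk protein mean of WT 2 lies among the KO libraries and that of WT 3 close above them.

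Lists of chaperones and of the unfolded protein response were lower by the preset camera test. The HSP70 family list of 15, which holds the targeted genes and Hspa1l, had a median of -0.24 (camera adjusted p = 0.00193, and 0.0516 at a mean count of at least 50; adjusted p = 0.289 with an estimated correlation), and of -0.11 without WT 1 (0.0278). The 12 members left without these had a median of -0.19, with 11 negative (camera adjusted p = 0.0112, a test chosen after seeing the data; adjusted p = 0.303 with an estimated correlation). None of the 12 passed over all genes in edgeR or DESeq2, and the endoplasmic reticulum chaperone Hyou1 (-0.51 ± 0.17 SE, and -0.30 without WT 1) passed adjusted over the list of 15 alone. The 18 other chaperones regulated by HSF1, the heat shock transcription factor, had a median of -0.15, and of -0.25 without WT 4 (camera adjusted p = 0.0130, against 0.0941 and 0.0538 without WT 2 or KO 2 and 0.112 with age as a covariate; adjusted p = 0.289 with an estimated correlation). Among them Hspb1 stood at -0.46 ± 0.15 and Hsp90ab1 at -0.32 ± 0.13. The unfolded protein and integrated stress response list had 19 of 20 members negative and a median of -0.41 (1.35e-05; adjusted p = 0.289 with an estimated correlation), with Calr at -0.51 ± 0.22 and Manf at -0.59 ± 0.25. Without WT 1 the median of this list was -0.16 (camera adjusted p = 0.0135), with Calr at -0.19 and Manf at -0.24. Immediate early genes, which tissue dissociation induces, had a median of -0.25 over 19 members, and of -0.11, -0.15 and -0.40 without WT 2, KO 3 or KO 5 (camera adjusted p = 0.00655, against 0.201 and 0.0954 without WT 2 or KO 3 and 0.761 with age as a covariate; adjusted p = 0.467 with an estimated correlation).

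Lists of proliferation, p53 target and skeletal muscle genes were higher by the preset camera test. Of 29 proliferation genes 23 were positive, with a median log2 fold change of 0.27, and of 0.15, 0.14 and 0.17 without WT 2, WT 4 or KO 4 (camera adjusted p = 0.000165, against 0.0878 without WT 2 and 0.317 with age as a covariate; adjusted p = 0.44 with an estimated correlation). Mki67 stood at 0.55 ± 0.32 (SE), or 0.36 without WT 2. The 13 p53 targets had a median of 0.27, and of 0.15 without KO 5 (0.0175, against 0.115 without KO 5, 0.198 without WT 1 and WT 4 and 0.157 with age as a covariate; adjusted p = 0.387 with an estimated correlation). Among them Cdkn1a, the cell cycle inhibitor p21, stood at 0.58 ± 0.24. The 10 skeletal muscle markers had a median of 0.51, and of 0.79 and 0.27 without WT 2 or WT 4 (0.00019, and 0.458 without WT 1 and WT 4; adjusted p = 0.303 with an estimated correlation), with titin (Ttn) at 0.81 ± 0.22, which passed adjusted over that list alone. Lists of hypoxia and glycolysis (median -0.10, camera adjusted p = 0.113), interferon response (0.02, 0.795), NF-kB targets (0.08, 0.509), genes flanking the Hsp72 locus (-0.05, 0.624) and mitochondrial mRNAs (-0.08, 0.795, the test's direction being up) were not called. This changed for 3 of them: the hypoxia list was lower without KO 3 (0.00254) and with age as a covariate (0.0269), and the interferon and mitochondrial lists were higher without WT 4 (0.0296 and 0.00584), while the interferon list was lower without WT 1 (0.0242). The flanking list holds Hspa1l, which rose by 5.16 on the log2 scale and was its only member called over all genes.

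Of the 33 lists tested, 20 were thus lower and 3 higher with the preset correlation, while none passed with an estimated correlation (lowest adjusted p = 0.289), by fry (0.186) or by exact permutation of library means (0.131). At an unadjusted p under 0.05 these tests found 3, 5 and 4 lists. With 126 assignments, exact permutation could pass a list after adjustment only if several lists reached its smallest p of 0.00794. With age as a covariate 14 were lower and 1 higher, 9 of the calls being lost and that of the hypoxia list gained, and without WT 1 and WT 4, 12 were lower and 1 higher. The age term rested largely on WT 2, so the changes with age may reflect that library rather than age. The first principal component of the 1000 most variable genes held 32.6% of their variance and ran from -30.2 in WT 1 to 25.2 in WT 2, with the KO libraries between -5.66 and 19.6. Correlations of log2 CPM across genes were 0.924 to 0.965 between WT libraries, 0.949 to 0.980 between KO libraries and 0.924 to 0.974 between the groups.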

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

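The tests of length and GC content, of fibroblast markers and of other splits were chosen after the results were seen; the age covariate and the screen for libraries far from the rest of their group were planned. It tested 382 groups of values (genes, list means and depth measures), of which 30 had such a library, or 7.85%, where chance gives about 1 in 20. That rate holds for independent, normally spread values. The flags of single genes, set on CPM, were all on the high side, and the lists share genes with them, so no excess over chance follows. WT 1 accounted for 16 of the 30 flags, KO 3 for 5, WT 2 and WT 4 for 3 each, KO 4 for 2 and KO 5 for 1.

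WT 1 stood above the other WT libraries for matrix genes other than collagens, cell-matrix receptors and the unfolded protein response. Its level was 92.1 CPM for Bgn (others 30.1 to 39.4), 250 CPM for Sparc (77.4 to 100), 132 CPM for Fbn1 (49.7 to 61.5), 234 CPM for Lamc1 (83.4 to 106) and 91.4 CPM for Sdc2 (49.7 to 53.3). It was 153 CPM for Tgfbr1 (82.4 to 92.9), 12.8 CPM for Tie1 (3.97 to 4.92), 1418 CPM for Calr (645 to 751), 444 CPM for Hyou1 (262 to 286), 220 CPM for Muc1 (135 to 141) and 97.7 CPM for Neu1 (68.5 to 72.9). Mean log2 CPM in WT 1 was 6.02 for matrix glycoproteins (5.03 to 5.16 in the others), 6.57 for basement membrane genes (5.91 to 6.02), 4.46 for matrix proteases (3.63 to 3.76), 7.08 for cell-matrix receptors (6.27 to 6.39) and 7.33 for the unfolded protein response (6.56 to 6.62). The collagen mean of WT 1 (6.55, against 6.31 to 6.44 in the others) was not flagged.

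Other libraries stood apart for fewer values. WT 2 had 565 CPM of the coagulation factor gene F3 (27.1 to 110 in the other WT libraries), 37.0 CPM of Ly6g6c (0.895 to 4.65) and 262 CPM of Fos (106 to 121). WT 4 had 34.0 CPM of Gm43305 (3.49 to 7.52), 8.28 CPM of the globin gene Hbb-bt (3.49 to 4.18) and 21.1% of its counts in its 10 most abundant genes (11.8% to 13.1%). KO 3 had 15.3 CPM of Adm (1.99 to 5.30 in the other KO libraries), a mean log2 CPM of 6.01 for hypoxia genes (5.16 to 5.39) and of 4.23 for genes flanking the Hsp72 locus (4.76 to 4.87), with 11.0% of fragments unmapped (19.7% to 21.8%) and 50.4% outside annotated features (39.6% to 41.7%). KO 4 had 4.51 CPM of Cdh11 (2.17 to 2.77) and 21.7 CPM of Egr3 (9.46 to 12.2). KO 5 had 10.4 CPM of S100a8 (0.903 to 2.96).

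The lower matrix lists were weighed against technical and cellular explanations. A bias by exon length or GC content is argued against as the whole cause, since the median log2 difference of the collagens was -0.61 before and -0.64 after correcting each library for both. The correction was partial for length: over protein-coding genes the rank correlation of exon length with the log2 difference was 0.166 before and 0.0769 after. A smaller share of fibroblasts may contribute and stays open: the collagen mean differed by -0.33 more than the fibroblast marker mean, with an exact permutation p of 0.127 (0.516 adjusted over 5 marker lists). Against pericyte, endothelial, macrophage and luminal markers the collagen mean differed by -0.16, 0.051, 0.0025 and -0.46. The collagens thus fell about as much as the endothelial and macrophage markers. Age as a covariate left both calls in place with the preset correlation (camera adjusted p = 1.19e-05 for the collagens and 3.82e-08 for the matrix glycoproteins). No list test without that preset was run with age, so this does not decide on age. Loss of Hsp72 itself, the difference the design names, and cells lost in dissociation stay open as well. Among 100 of the 126 possible splits of the libraries, 3 gave a collagen p with the preset correlation as small as the real 2.61e-10 (smallest other 2.79e-13) and 6 a matrix glycoprotein p as small as the real 3.69e-10 (smallest other 1.64e-15); with adjusted p of 0.175 and 0.131 by exact permutation of library means, chance is not firmly excluded for either list.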

How the results depend on the processing

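Leaving out WT 1 and WT 4, leaving out chromosomes 14 and 17, the HSP70 list without the targeted genes and Hspa1l, the permutation of list means and the length and GC correction were chosen after seeing the data; the other alternatives were planned. Hspa1b kept its direction and call under every alternative run that tested it; the fit without chromosomes 14 and 17 did not. RLE and upper-quartile factors left the counts at 8 higher and 5 lower. Among named genes 2425 values kept direction and side of the threshold, 39 lost the call, 13 gained it and 48 reversed; among lists these numbers were 473, 118, 7 and 27. The cause was not tested, except where fewer genes or libraries entered by construction. Low depth limits genes near the floor of 0.482 to 0.680 CPM.

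Genes higher and lower numbered 30 and 38 by DESeq2 (13 genes shared with edgeR), 14 and 15 without a count filter, 4 and 2 at a mean count of at least 50, 8 and 2 with age, 1 and 0 without chromosomes 14 and 17 (edgeR; 1166 genes had an unadjusted p under 0.05 with all chromosomes), and 5 to 9 and 1 to 4 with 1 library left out. Hspa1a had too few counts for the mean count filter; its log2 fold change was -3.16 with age (adjusted p = 0.0858), -2.998 without WT 1 and WT 4 (0.306) and -3.61 to -2.89 with 1 library left out. Lists lower and higher numbered 0 and 0 with an estimated correlation, by fry and by exact permutation, 12 and 1 without WT 1 and WT 4, 14 and 1 with age, and 2 to 5 lists were higher with 1 library left out (5 without WT 4). The adjusted p of the collagens was 0.289, 0.186 and 0.175 with an estimated correlation, by fry and by exact permutation, and that of the matrix glycoproteins 0.289, 0.217 and 0.131.

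Library numbers were not treated as pairs, since not every pair's deviations correlated over 0.1 (-0.02, 0.38, 0.11 and 0.38) and the labels give them no meaning; 3 of 4 pairs matched best with their own number, a hint from the data. With the number as a block, 5 genes were higher and 5 lower, 7 of them shared. No WT library is numbered 5, so KO 5 adds nothing to the genotype comparison under the block, which lowers its power. Not past the threshold under the block were Gm3375 and Dmtn (adjusted p = 0.0775 for both), Ppp1r3e (0.0787), Cilp (0.133) and Gm15918 (0.163). Under the block Hspa1a stood at -3.23 (adjusted p = 0.1695), and reversed log2 fold changes were -0.44 for S100a8, -0.39 for Csf3r and 0.078 for Zbtb46. List calls lost under the block were basement membrane (adjusted p = 0.111), luminal (0.0617) and p53 targets (0.177), and T and NK cell markers gained one (0.000961). Lists that reversed under the block had adjusted p of 0.920 (basal), 0.256 (interferon), 0.979 (NF-kB) and 0.593 (mitochondrial).

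Without WT 1 and WT 4, which were chosen for their casein counts, so that the casein values say nothing, log2 fold changes reversed to 0.18 for Cdh11, 0.021 for Mcam, 0.12 for Cd3g, 0.10 for Gzmb, 0.15 for Ighm, 0.38 for Csn1s2a, 0.15 for mt-Nd6, 0.31 for mt-Cytb, 0.39 for mt-Co1 and 0.26 for mt-Nd5, and the interferon list reversed (adjusted p = 0.949). With age they reversed to 0.50 for F3, -0.45 for S100a8, -0.29 for Csf3r, 0.43 for Cfd, 0.31 for Lipe and -0.016 for Adm, and lists reversed with adjusted p of 0.121 (adipocyte), 0.713 (basal) and 0.116 (genes flanking the Hsp72 locus). With limma-voom they reversed to 0.079 for mt-Cytb, 0.11 for mt-Co1 and 0.072 for mt-Nd5. Further lists reversed by exact permutation (basal 0.968, flanking 0.917), by fry (flanking 0.924), after the length and GC correction (flanking 0.916, mitochondrial 0.936) and at a mean count of at least 50 (Schwann 0.785).

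With 1 library left out, log2 fold changes that reversed ranged from -1.46 to 0.48 for F3, -0.60 to 0.11 for Cd8a, -0.70 to 0.26 for Gzmb, -0.62 to 0.022 for Ighm, -0.49 to 0.68 for S100a8, -0.36 to 0.17 for Csf3r, -0.24 to 0.083 for Zbtb46, -0.71 to 0.12 for Cfd, -0.43 to 0.088 for Lipe, -0.052 to 0.23 for Sox10, -0.50 to 0.32 for mt-Nd6, -0.33 to 0.48 for mt-Cytb, -0.32 to 0.52 for mt-Co1 and -0.31 to 0.46 for mt-Nd5. Adjusted p of lists that reversed ranged from 0.0640 to 0.866 for T and NK cells, 0.00668 to 0.919 for adipocytes, 0.483 to 0.995 for basal, 0.0242 to 0.971 for interferon, 0.129 to 0.806 for flanking and 0.00584 to 0.877 for mitochondrial genes.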

Other observations

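The tests of the Hoxb genes as a cluster, of the chromosome 14 segment, of the pseudogenes' parents and of other splits, and the exact permutation of list means, were chosen after the results were seen; edgeR, DESeq2, the library number as a block, libraries left out, fry and the estimated correlation were planned. Genes of the Hoxb cluster on chromosome 11, which encode transcription factors of body patterning, had positive fold changes; they were chosen after their values were seen. All 4 Hox genes tested belonged to this cluster and had log2 fold changes of 1.94 ± 0.56 (Hoxb4, SE), 1.70 ± 0.57 (Hoxb3), 2.38 ± 0.44 (Hoxb3os) and 1.26 ± 0.53 (Hoxb2), between 96318267 and 96354691. Hoxb3os, an opposite-strand transcript, was higher in every KO library than in every WT library, at 10.0 ± 3.29 CPM against 1.88 ± 1.11 CPM (SD). None passed edgeR's test over all genes, where the lowest adjusted p = 0.166, and all 4 had an unadjusted p under 0.05; DESeq2 called Hoxb3os (adjusted p = 2.87e-05). Hoxb3os shares 2250 exon bases with Hoxb3 and 953 with Hoxb2, so reads in these bases cannot be assigned without the strand setting.

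The called genes of chromosome 14, weighed as a group, spanned 16.3 Mb holding 160 tested genes. A gain or loss of the segment is argued against by the median log2 fold change of these genes, 0.00614, with quartiles of -0.21 and 0.21. RNA of another cell type was not excluded: the test of called genes on this chromosome (7 of 13 against 479 of 14665 tested, Fisher's exact p = 5.50e-08) restates the count that prompted it, and Gm15918 and Xkr6 can share part of their reads. A strain segment around a differing locus could account for changes in both directions and stays open: of the 153 other genes of the segment 3.92% had an unadjusted p under 0.01, against 1.45% on other chromosomes (Fisher's exact p = 0.0261, and 0.0737 without Psmb5), but 6 of 79 windows of as many genes elsewhere held as many such genes. The segment ended at the called genes, which this comparison left out. Of 55 genes called by DESeq2 alone, 8 lay on chromosome 14 and 4 on chromosome 17. Of those on chromosome 14, Fndc3a (DESeq2 adjusted p = 1.26e-06, edgeR 0.0825) and Lrch1 (0.000278 and 0.166) lay outside the segment. An effect of Hsp72 loss on the called genes was not tested apart from a strain segment.

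The pseudogene calls were weighed as a pair. For Gm3375, a candidate explanation is that reads of Psmb5, its parent gene, were counted at the copy in KO: Psmb5, chosen after its values were seen, stood at 12.3 ± 2.22 CPM in WT and 6.33 ± 1.06 CPM in KO, and the summed CPM of both differed by -0.0163 on the log2 scale. Psmb5 lies on chromosome 14 at 54614119, inside the segment above, and is 1 of its 6 other genes with an unadjusted p under 0.01, so that count may hold the same read shift; a sequence variant that would move the reads was not tested. For Gm28438, a mitochondrial variant between the colonies could move reads from mt-Nd3 to the copy, but mt-Nd3 had 5 unique counts in WT and 0 in KO (exact binomial p = 0.0110), too few to decide.

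Other splits of the 9 libraries were counted for each number of calls, over 100 of 126 splits with the real one included. For genes higher in KO 1 split gave as many as the real 8 (highest other 1), for genes lower 1 gave as many as the real 5 (highest other 2), and for lists lower 1 gave as many as the real 20 (highest other 17). The gene counts include the deleted genes and Hspa1l, which a mixed split cannot reproduce, so these comparisons say nothing on chance for the rest. Without these 3 genes, 1 split gave as many as the real 7 higher (highest other 1), most of them on chromosome 14. Gm15918 can share reads with Xkr6 and Gm3375 may hold reads of Psmb5, so the 7 may not be separate events. A difference fixed between the groups cannot be reproduced by a mixed split, so this comparison does not settle chance for the 7 genes. For genes lower, without the same 3 genes, 2 splits gave as many as the real 2 (highest other 2), so chance is not firmly excluded there. Without chromosomes 14 and 17, 3 splits gave as many as the real 1 higher (highest other 1) and 100 as many as the real 0 lower (highest other 2), so chance is not firmly excluded for the first count and cannot be excluded for the second. The gene then called was Gm3375, with 0 counts in each WT library and 26 to 39 in each KO library (edgeR adjusted p = 0.000805 over all genes), kept whichever library was left out but lost with the library number as a block (0.0775). The comparison under the block makes no use of KO 5. The list count rests on the preset correlation and on 1 direction: another split called 22 lists in both directions against the real 23. No list passed by fry or an estimated correlation, or by exact permutation, which could hardly pass one after adjustment. Chance is thus not firmly excluded for the list count. For lists higher 76 splits gave as many as the real 3 (highest other 18), so chance cannot be excluded. At an unadjusted p under 0.05, 15 splits gave at least the real 1166 genes, and the highest other gave 3489, several times as many, which points to a structure of the samples other than genotype. That split set WT 2, WT 4, KO 2, KO 4 and KO 5 against the rest. These libraries had the highest unmapped shares, 19.8% to 27.1%, against 11.0% to 19.7% in the rest. The cause was not tested, and no gene test was adjusted for these shares.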
